A study of Mus musculus with 32 samples.

How the data were processed

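Chromatin accessibility was profiled by ATAC-seq, in which a transposase cuts and tags open DNA, in liver endothelial cells and Kupffer cells (the resident macrophages of the liver) isolated from male C57BL/6J mice. The labels describe 32 libraries in 8 groups, with 16 libraries per cell type. Each cell type was sampled at ZT10 and ZT22 (hours after lights on), from wild-type mice and from mice lacking both REV-ERBs, the heme-binding repressors of the circadian clock, in hepatocytes, with 4 replicates per group. Per the labels' protocols, a fixed number of isolated cells was transposed in a digitonin-containing mixture, and the purified fragments were amplified.

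The files used here are 2 peak lists that the authors deposited, 1 per cell type. Each list holds 3 columns (chromosome, start and end), with no score, height, count, p-value or library of origin for any peak. The list names mark the peaks as nucleosome-free-region peaks. Bowtie and HOMER and the genome build mm9 are named in the submitters' processing notes, without versions; the peak threshold, the treatment of transposase offsets, the selection of short fragments and the way in which libraries were pooled or merged are not given in the sources used here. Because the lists carry no values per library, the depth is unknown, no mean ± SD can be given, and the comparisons of knockout with wild type and of ZT22 with ZT10 were not analysed here. No peak overlapped or touched another within either list, so each list is already a set of distinct intervals. A peak missing from a list was not called by the authors in that cell type; its accessibility there is not known to be zero.

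The only annotation at hand was a gene table on GRCm38. The last peak lay beyond the last gene of that table on 10 of 20 chromosomes, by up to 7.19 Mb on chromosome 7, and the submitters name mm9. The coordinates were therefore taken as mm9, and no gene, exon or promoter was assigned to a peak. The 13 gene lists, the 22 sequence motifs and the promoter classes fixed before the data were examined were therefore not used, and under the rule fixed for that case only windows of the genome are named. Positions are given on mm9, counted from 1.

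A peak was called shared where it overlapped a peak of the other list by at least 1 bp and restricted (endothelial-only or Kupffer-only) otherwise. Overlaps were computed with NumPy 2.4.6 in Python 3.11.15, and the counts of shared peaks were checked against bedtools 2.31.1, which gave identical numbers. The chance level of sharing came from 100 circular shifts of the other list within each chromosome. Intervals for shares are exact (Clopper-Pearson) 95% binomial intervals from SciPy 1.17.1; they treat peaks as independent, cover counting error only and say nothing about variation between mice. Chromosomes were compared through 95% percentile intervals from 1000 bootstrap samples of 1 Mb blocks. Restricted peaks were counted by their centres in non-overlapping windows of 100 kb, and the 5 windows with the most peaks of each kind were named, ties at the last rank included, which gave 5 endothelial and 7 Kupffer windows. Window counts and the cell type of neighbouring restricted peaks were set against 100 shuffles of the endothelial-only and Kupffer-only labels over all restricted peaks. A second set of 100 shuffles exchanged labels only among peaks with a similar distance to their nearest restricted neighbour. The minimum of 10 endothelial-only or 20 Kupffer-only peaks for a dense window, the second set of shuffles and the shuffled number of windows dense in both kinds were chosen after the data were seen. No p-value was computed, since 2 lists give no replicates and peaks are not replicates.

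The overlap procedure was tested on simulated data: with 19.8% and 60.1% of the 91453 endothelial peaks copied into a simulated Kupffer list with a small displacement, the chance-corrected estimates were 19.7% and 60.0%. Every copy still overlapped its source, and all other peaks were placed at random. The test therefore checks the counting and not lists whose restricted peaks cluster. The shares of shared peaks given below are not corrected for chance. Alternatives covered the overlap that counts as shared, the wider 50% of each list, lists of equal length, random placement as the chance level, joining of close peaks, removal of unplaced, mitochondrial and Y sequences, removal of peaks of the smallest common width and other window sizes. No columns of samples outside the series were present.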

Results

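The study profiled open chromatin in liver endothelial cells and Kupffer cells of wild-type mice and of mice without REV-ERBα and REV-ERBβ in hepatocytes, to ask how the hepatocyte clock acts on other cell types of the liver. The 32 ATAC-seq libraries comprise 4 replicates of each cell type, time (ZT10 or ZT22) and genotype. The files hold 1 peak list per cell type with positions alone, so the comparison that can be made is between endothelial cells and Kupffer cells. The effects of genotype and time were not analysed here, and no value below has a replicate.

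The Kupffer cell list was the longer of the pair. It held 137684 nucleosome-free peaks covering 28.3 Mb of mm9, and the endothelial list held 91453 peaks covering 19.2 Mb, a ratio of 1.51 Kupffer peaks per endothelial peak. Peaks were of similar width in both cell types, with a median of 199 bp (quartiles 151 and 232 bp) in Kupffer cells and 198 bp (quartiles 151 and 244 bp) in endothelial cells. A width of exactly 151 bp was the smallest common value, and all but 2 endothelial and 3 Kupffer peaks were at least that wide. Peaks of 151 bp made up 34.5% of the endothelial list (95% exact binomial interval 34.2% to 34.8%) and 26.0% of the Kupffer list (25.8% to 26.3%). How the libraries of a cell type were merged into its list is not given, so peak width reflects that step as well as the site, and whether 151 bp marks a peak called in 1 library is not known. Kupffer peaks lay closer together, with a median gap of 3830 bp to the next peak against 6302 bp in endothelial cells. Only 110 endothelial and 142 Kupffer peaks fell outside chromosomes 1 to 19 and X, and 1 Kupffer peak lay on the mitochondrial genome. The read depth behind either list is unknown, so a longer list is not by itself a larger number of accessible sites.

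Most endothelial peaks were also called in Kupffer cells, and most Kupffer peaks were not called in endothelial cells. Of the endothelial peaks, 53324 or 58.3% overlapped a Kupffer peak (58.0% to 58.6%), against 2.28% when the Kupffer list was shifted along the chromosomes (range 2.06% to 2.52% over 100 shifts). Of the Kupffer peaks, 53800 or 39.1% overlapped an endothelial peak (38.8% to 39.3%), against 1.52% by chance (1.38% to 1.74%). Sharing was thus 25.6-fold over chance for endothelial and 25.7-fold for Kupffer peaks. The shifts move peaks over the whole span of a chromosome. The fold therefore includes any tendency of both lists to lie in the same regions, which was not separated from sharing of single sites. The fold depends on the definition: it was 55.3 and 55.0 with an overlap of at least 50% of both peaks, and 9.93 and 10.5 with peaks within 500 bp counted as shared. The lists together defined 174603 distinct sites, of which 30.1% were in both, 21.8% in endothelial cells alone and 48.0% in Kupffer cells alone. In base pairs, 9.42 Mb were covered by both lists out of 38.1 Mb covered by either, or 24.7%. Shared peaks sat at nearly the same place, with a median distance of 24.5 bp between centres, although only 192 intervals were identical to the base. The numbers of shared peaks in the lists being nearly equal, the difference between the 2 shares is that between the list lengths.

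The 38129 endothelial-only peaks and the 83884 Kupffer-only peaks often lay near peaks of the other cell type. A Kupffer peak lay within 1 kb of 25.9% of endothelial-only peaks (25.5% to 26.4%), against 10.1% with shifted lists. An endothelial peak lay within 1 kb of 22.5% of Kupffer-only peaks (22.2% to 22.8%), against 7.22%. Within 10 kb the shares were 70.6% for endothelial-only and 68.2% for Kupffer-only peaks, against 38.9% and 33.7% by chance. The values from shifted lists at both distances include direct overlaps, which restricted peaks cannot have by definition, so the measures are not fully alike. The remaining peaks, 29.4% and 31.8% of each kind, had no peak of the other cell type within that distance. These shares depend on the definition of sharing: with peaks up to 500 bp apart counted as shared, 65.6% of endothelial and 48.0% of Kupffer peaks were shared.

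Wide peaks were shared more often than narrow ones in both cell types. In endothelial cells the shared part was 46.1% of peaks up to 151 bp wide (45.6% to 46.7%), 65.9% of those of 201 to 250 bp (65.3% to 66.5%) and 73.1% of those over 400 bp (70.8% to 75.4%). In Kupffer cells it was 39.8% of peaks of 201 to 250 bp (39.3% to 40.2%) and 69.3% of those over 400 bp (66.8% to 71.7%). Below that range the order differed between the cell types. Kupffer peaks up to 151 bp wide were shared in 35.8% of cases (35.3% to 36.3%), more than the 28.7% of those of 152 to 180 bp (28.0% to 29.5%), whereas endothelial peaks of 152 to 180 bp were shared in 55.8% of cases (54.6% to 56.9%). The chance level stayed below 4% in each width class, with a highest value of 3.63%. Endothelial-only peaks had a median width of 171 bp and shared endothelial peaks one of 210 bp. The corresponding medians in Kupffer cells were 194 and 207 bp.

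**Figure D1:**
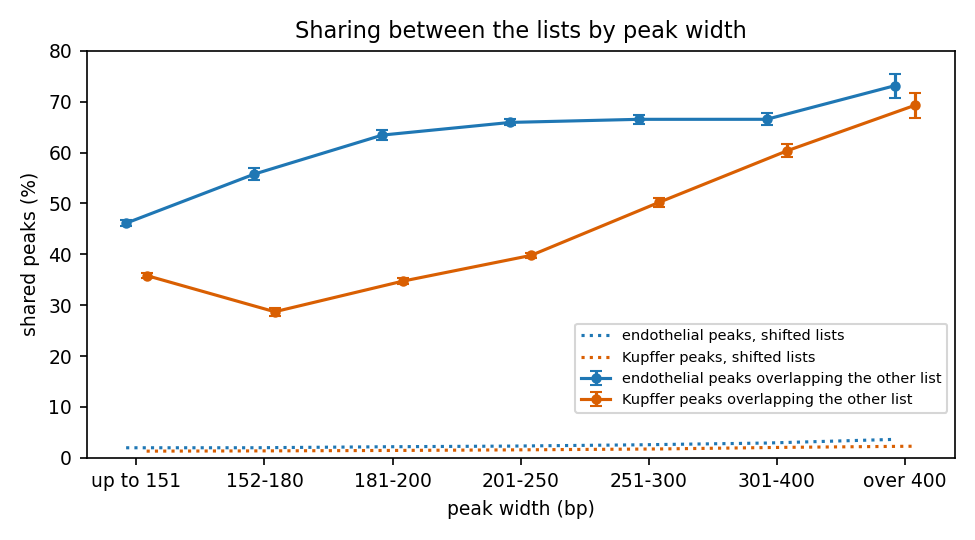
Share of endothelial peaks (blue) and Kupffer peaks (orange) that overlap the other list, in percent, by peak width in bp; bars are exact 95% binomial intervals and dotted lines the mean share with shifted lists. Sharing reaches 73.1% and 69.3% in peaks over 400 bp, and the Kupffer series has its lowest value, 28.7%, at 152 to 180 bp.

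Chromosomes differed in the balance between the cell types. Over chromosomes 1 to 19 and X there were 1.51 Kupffer peaks per endothelial peak (95% block bootstrap interval 1.48 to 1.53). Chromosome 11, at 1.65 (1.56 to 1.74), and the X chromosome, at 1.69 (1.54 to 1.84), had intervals above that of the genome, and chromosome 8, at 1.37 (1.28 to 1.46), had an interval below it. The other 17 chromosomes had intervals that overlapped the genome's; chromosome 19 had a ratio as high as that of X, at 1.69, with a wider interval (1.53 to 1.87). The intervals of 5 chromosomes (8, 11, 13, 19 and X) missed the common ratio itself, where 1 of 20 intervals of 95% would be expected to do so by chance. The bootstrap treats blocks of 1 Mb as independent, yet the longest run of endothelial-only peaks, given below, spanned 2690 kb. The intervals may therefore be too narrow, and the number that missed the ratio too high. Chromosome 11 was also the most densely covered, with 49.1 endothelial and 80.8 Kupffer peaks per Mb. The X chromosome had the fewest peaks per Mb in both cell types, 10.3 in endothelial and 17.3 in Kupffer cells, against 36.3 and 54.5 on the autosomes together. The lowest autosome, chromosome 14, had 28.8 and 43.0. The mice were male, with 1 copy of the X chromosome, which may lower the number of calls on it in both lists. Neither copy number nor depth was separated here from the density of peaks or the ratio on X. The share of endothelial peaks that were shared ran from 55.0% to 62.1% across the 20 chromosomes, and that of Kupffer peaks from 35.3% to 42.5%.

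**Figure D2:**
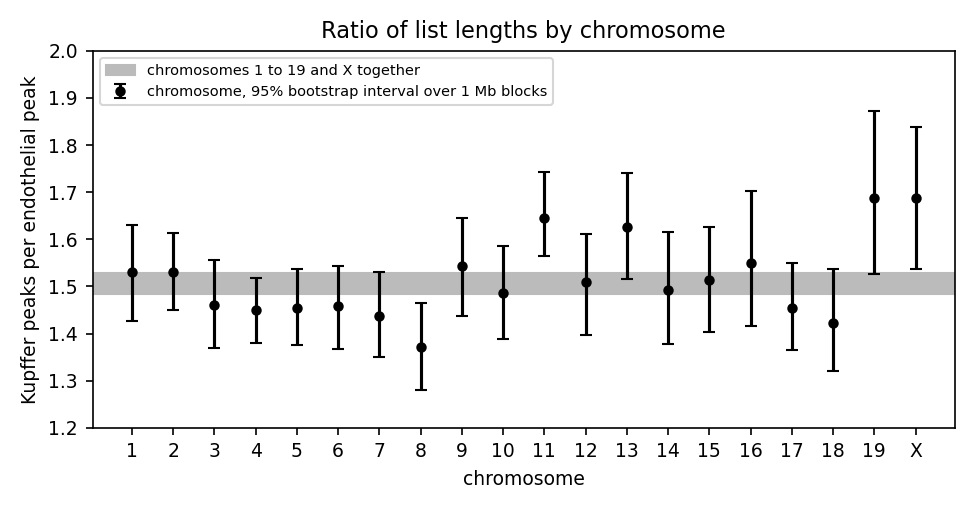
Kupffer peaks per endothelial peak on each chromosome (points) with 95% bootstrap intervals over 1 Mb blocks; the grey band is the interval for chromosomes 1 to 19 and X together, 1.48 to 1.53, and the vertical axis does not start at 0. The whole intervals of chromosomes 11 and X lie above the band and that of chromosome 8 below it; chromosome 19 has the highest point, with an interval that reaches into the band.

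In windows of 100 kb, restricted peaks of 1 cell type gathered more than shuffled labels gave. Most of the dense windows also held restricted peaks of the other type. Of 17029 windows of 100 kb with a restricted peak, 407 held at least 10 endothelial-only peaks, against 148 to 198 when the cell-type labels were shuffled over all restricted peaks and 101 to 154 when they were shuffled among peaks of similar spacing. At least 20 Kupffer-only peaks were found in 250 windows, against 95 to 129 and 119 to 154 in the same shuffles. Few dense windows were exclusive to their kind. Of the 407 dense endothelial windows 46 held no Kupffer-only peak, and of the 250 dense Kupffer windows 46 held no endothelial-only peak. The median number of restricted peaks of the other type was 6 in the former and 2 in the latter. Windows dense in both kinds numbered 4, against 12 to 28 and 11 to 21 in the same shuffles. The shuffles keep the total number of restricted peaks in each window. If windows dense in either kind fell independently of each other among the 17029 windows, 5.98 would be expected, close to the observed number. Across the same windows, the numbers of endothelial-only and Kupffer-only peaks were less closely related than shuffled labels gave, with a Spearman coefficient of 0.16 against 0.61 to 0.63. Windows without any restricted peak were left out of both, which can lower the coefficient, so only its difference from the shuffles is of use. Windows are not independent replicates, and the counts moved with the definition of a peak: with restricted peaks within 1 kb of each other counted once, 198 endothelial and 19 Kupffer windows reached those minimums, against 45 to 83 and 3 to 15 in shuffles. They also moved with the window: at 500 kb, where the same minimums were reached by 1613 and 1813 of 4508 windows, both counts were below the shuffled ranges (1673 to 1733 and 1815 to 1875).

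The window with the most endothelial-only peaks lay on chromosome 17 between 74100001 and 74200000, with 23 endothelial-only peaks, no Kupffer-only peak and 2 shared endothelial peaks. The next window, on chromosome 4 between 137000001 and 137100000, held 22 endothelial-only and 4 Kupffer-only peaks. The other 3 windows each held 21 endothelial-only peaks. They lay on chromosome 15 between 93300001 and 93400000, with 3 Kupffer-only peaks, on chromosome 6 between 88700001 and 88800000, with 6, and on chromosome 8 between 113200001 and 113300000, with 5. From the overall share of endothelial-only peaks among restricted peaks, 31.2%, these 5 windows would have held between 7.19 and 8.44. The highest count in any window was 14 to 22 over the shuffles of all restricted peaks and 13 to 20 over the shuffles by spacing, so that 1 of the 5 windows, that on chromosome 17, lay above both ranges. That rank depends on the definition of a peak. Without peaks of 151 bp the 5 windows held 17, 14, 18, 18 and 14 endothelial-only peaks in the order given, and the fullest window of the label shuffles 12 to 17, so that the windows on chromosomes 15 and 6 lay above the range and that on chromosome 17 within it. The highest count without peaks of 151 bp was 20, in a window not among these 5. With restricted peaks within 1 kb counted once, the windows on chromosomes 17 and 15, with 18 and 19, were above the shuffled 12 to 17. With peaks within 500 bp counted as shared, the windows on chromosomes 17 and 8 each held 21, above the shuffled 12 to 20, and the others lay within it.

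Kupffer-only peaks were most numerous on chromosome 19 between 55800001 and 55900000, with 37, beside 2 endothelial-only and 4 shared endothelial peaks. On chromosome 2 between 90300001 and 90400000 there were 36 Kupffer-only peaks, no endothelial-only peak and 6 shared ones. Chromosome 9 held 34 Kupffer-only and 2 endothelial-only peaks between 95500001 and 95600000, and chromosome 5 held 33 and 5 between 102400001 and 102500000. Windows with 32 Kupffer-only peaks lay on chromosome 13 between 20200001 and 20300000, on chromosome 2 between 166500001 and 166600000 and on chromosome 9 between 45000001 and 45100000, with 1, 6 and 0 endothelial-only peaks. In these 7 windows the overall share would give between 22 and 26.8 Kupffer-only peaks. Shuffles of all restricted peaks reached 26 to 33 in their fullest window and shuffles by spacing 27 to 34, so the windows with 37 and 36 lay above both ranges and those with 32 to 34 did not. With restricted peaks within 1 kb counted once, both of these windows fell to 25, inside the shuffled 20 to 28, and without peaks of 151 bp both fell to 27, inside 23 to 29, while the window on chromosome 2 at 166500001 held 31, above that range. With peaks within 500 bp counted as shared, the windows with 37 and 36 held 32 and 34, above the shuffled 23 to 31. The annotation of these regions was not used here, since the gene table at hand is on another assembly.

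**Figure D3:**
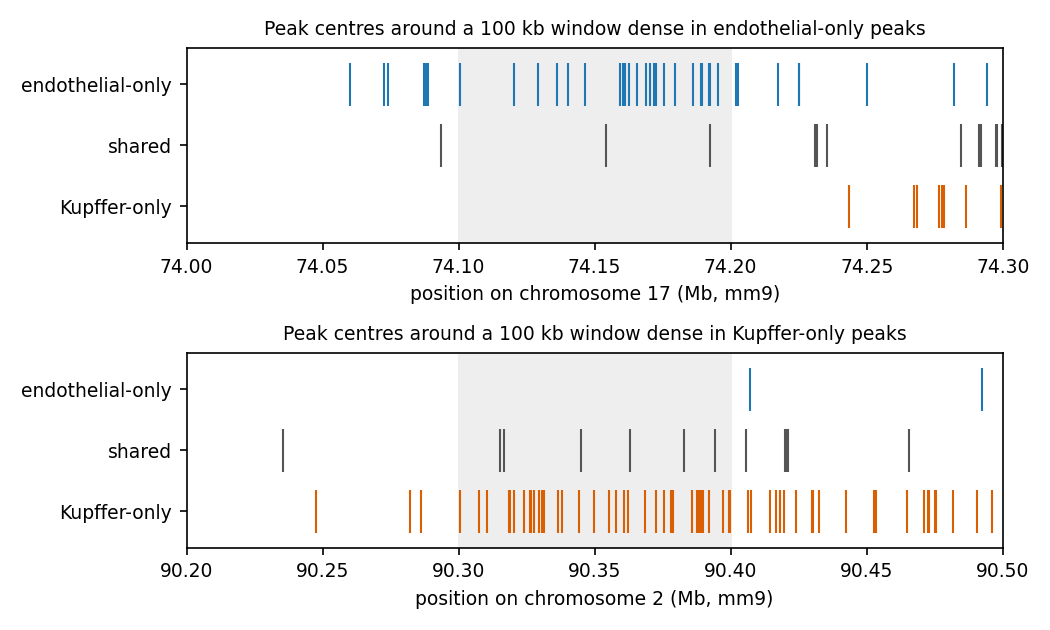
Centres of endothelial-only (blue), shared (grey, positions from the endothelial list) and Kupffer-only (orange) peaks along mm9, in Mb, around a window on chromosome 17 (top) and one on chromosome 2 (bottom); the shaded parts are the 100 kb windows. The upper window holds 23 endothelial-only and no Kupffer-only peaks, and the lower one 36 Kupffer-only and no endothelial-only peaks. The fullest Kupffer window, on chromosome 19 with 37 Kupffer-only and 2 endothelial-only peaks, is not shown. Windows without the other type are not typical: they were 46 of 407 dense endothelial and 46 of 250 dense Kupffer windows.

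Neighbouring restricted peaks were of the same cell type more often than shuffled labels gave. At gaps of up to 1 kb, 79.1% of 24131 consecutive restricted peaks were of the same type, and at gaps of 1 to 5 kb 68.6% of 34294 were. The share was 67.8% at 5 to 20 kb and 65.1% at 20 to 100 kb. Shuffles over all restricted peaks gave between 56.2% and 58.3% in these 4 classes, and shuffles among peaks of similar spacing between 53.8% and 60.6%. Over 100 kb, with 3768 pairs, the observed 55.3% lay within the range of those shuffles (54.8% to 59.6%) and above that of the shuffles among peaks of similar spacing (48.6% to 52.9%). The latter allow for the make-up of sparse regions, where endothelial-only peaks were 50.9% of the pairs at that gap. The pooled share hides a difference between the types. At 1 to 5 kb and 5 to 20 kb, 47.2% and 47.8% of endothelial-only peaks were followed by an endothelial-only peak. The next peak was thus more often Kupffer-only, although endothelial-only peaks made up only 29.8% and 30.8% of these classes. Kupffer-only peaks were followed by their own kind in 77.7% and 76.6% of cases.

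**Figure D4:**
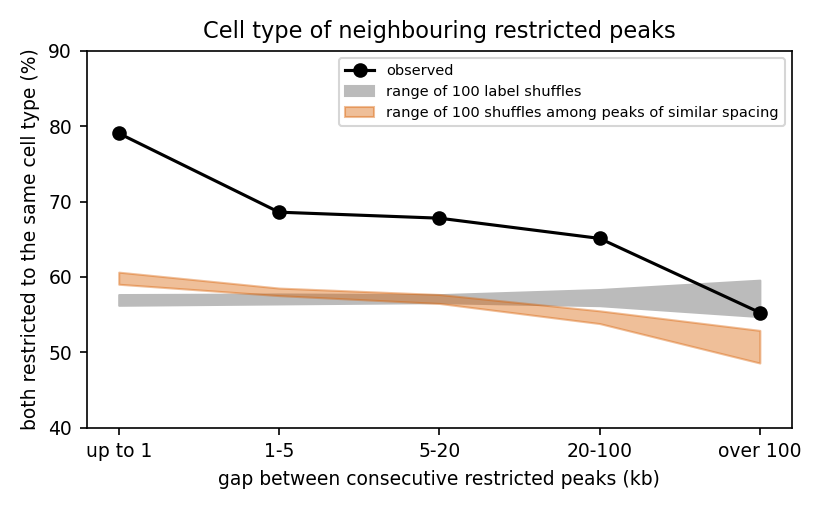
Share of consecutive restricted peaks that belong to the same cell type, in percent, by the gap between them in kb; black points are observed, and bands are the ranges of 100 label shuffles over all restricted peaks (grey) and among peaks of similar spacing (orange). The share falls from 79.1% to 65.1% up to 100 kb and stays above both bands there; the vertical axis does not start at 0.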

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

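Sharing stayed above chance in each setting run, and the Kupffer list stayed the longer one when close peaks were joined, when unplaced, mitochondrial and Y sequences were left out and when peaks of 151 bp were left out. Requiring an overlap of at least 50% of both peaks left 52.0% of endothelial and 34.5% of Kupffer peaks shared, 55.3-fold and 55.0-fold over chance. Counting peaks within 500 bp as shared gave 65.6% and 48.0%, 9.93-fold and 10.5-fold over chance. In the wider 50% of each list 47.1% and 31.4% were shared, and without peaks of 151 bp 57.0% and 33.8%; the latter setting, joining within 500 bp and counting restricted peaks within 1 kb once were chosen after the data were seen. With the Kupffer list reduced at random to the endothelial length, 39.2% of endothelial and 39.2% of Kupffer peaks were shared, the latter against 39.1% of the full Kupffer list. These 3 settings remove partners from the lists by construction, so the lower shares among them say nothing about the cell types or about stricter peaks. Leaving out peaks of 151 bp reduced the endothelial list to 59922 peaks. Windows with at least 10 endothelial-only peaks numbered 83 at 50 kb, 1613 at 500 kb, 245 with peaks within 500 bp counted as shared, 198 with restricted peaks within 1 kb counted once and 160 without 151 bp peaks. For at least 20 Kupffer-only peaks the numbers were 4, 1813, 131, 19 and 106. At 500 kb, where the same minimums admit a large part of the windows, both counts fell below the shuffled ranges, 1673 to 1733 and 1815 to 1875; in the other settings they were above them. Of 44 alternative values, 20 stayed within the binomial interval of a share or within 1.5 times a count or ratio, and 24 moved further. No paired analysis was possible because the lists hold no values per library; for the same reason no replicate could be left out and no other normalization or count filter was run. Alternatives for promoter classes, gene lists and motifs were not run, as no annotation or sequence of mm9 was used. No peak score was given, so a stricter peak threshold was not run. Depth, which the lists do not record, limits every statement about a peak missing from a list.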

Other observations

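The tests of the length of the Kupffer list, of shared peaks in dense windows and of partner widths among all Kupffer peaks, the shuffles by spacing and the tables of isolated restricted peaks and of uninterrupted runs were chosen after the results were seen. Predictions for the other tests were written before those tests. The bound for partner widths among shared peaks was set close to a share already observed. The more isolated a restricted peak was, the more often it was endothelial-only. Among restricted peaks with another restricted peak within 1 kb, 27.7% were endothelial-only (27.2% to 28.1%). The share was 33.2% at a distance of 5 to 20 kb, 43.5% at 20 to 100 kb and 62.7% (59.7% to 65.7%) over 100 kb, where there were 658 endothelial-only and 391 Kupffer-only peaks. Without peaks of 151 bp the series went from 22.3% to 58.7% (53.7% to 63.5%), so it does not rest on peaks of the smallest width. Distances were taken to restricted peaks only, and shared peaks were ignored. Kupffer-only peaks were more numerous, 83884 against 38129, and neighbours were often of the same type. A Kupffer-only peak can therefore have a close restricted neighbour more often for that reason, which was not separated from a trait of endothelial-only sites.

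Long stretches of the genome held restricted peaks of 1 cell type alone. The longest endothelial run, 47 endothelial-only peaks with no Kupffer-only peak between them, lay on chromosome 10 from 107636177 to 110326337. Runs of 42 and 39 endothelial-only peaks lay on chromosome 16 from 85901003 to 87325179 and on chromosome 4 from 57537427 to 57893178, and the longest run was 8 to 15 in shuffles over all restricted peaks and 8 to 14 in shuffles among peaks of similar spacing. The longest Kupffer runs held 77 Kupffer-only peaks on chromosome 8 from 85367729 to 86169298, 67 on chromosome 10 from 121971600 to 122291086 and 66 on chromosome 1 from 139648005 to 140234395, against 23 to 40 and 22 to 43 in the same shuffles. Shared peaks can lie within these runs.

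The first pattern is that restricted peaks lay next to restricted peaks of the same cell type more often than shuffled labels gave. Of consecutive restricted peaks at most 1 kb apart, 79.1% were of the same type, against 59.0% to 60.6% in shuffles among peaks of similar spacing. If 1 open site divided into adjacent peaks were the whole cause, the excess would end at larger gaps, but 67.8% were of the same type at 5 to 20 kb, where those shuffles gave 56.5% to 57.7%. Windows of 100 kb missing from 1 list as a whole are argued against by the shared peaks present in 94.6% of the dense endothelial windows and 97.6% of the dense Kupffer windows. The median was 6 shared peaks per window for either kind. A gap in 1 list over part of a window is not excluded by this test. Regulatory regions used by 1 cell type over long distances are a hypothesis that may account for the 65.1% at 20 to 100 kb, against 53.8% to 55.5%; a difference in local coverage or background between the lists stays open, since they record neither.

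The second pattern is the greater length of the Kupffer list. Division of open sites into more adjacent peaks is argued against as the whole cause, since joining peaks within 500 bp left 1.43 Kupffer peaks per endothelial peak. Peaks of 151 bp made up 9.33% of the Kupffer excess, so by count most of the excess consisted of wider peaks. This is a description of the lists and not a test. That value replaced an earlier one, the ratio of 1.70 without 151 bp peaks. The ratio decides nothing because the lower share of these peaks in the Kupffer list fixes its direction. The replacement and its bound of 50% were set with the counts already known. The same lower share, 26.0% against 34.5%, keeps the replacement below 26.0%, so the bound could not be reached. Deeper sequencing or more libraries behind the Kupffer list cannot be told apart from a larger number of open sites, because the ratio of 1.51 comes with no read totals and no calls per library.

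The third pattern is that Kupffer peaks of 151 bp were shared more often than those of 152 to 180 bp. Their position beside other peaks is argued against as the whole cause: among peaks with no other Kupffer peak within 1 kb, 37.5% of those of 151 bp were shared (36.9% to 38.2%), against 25.6% of those of 152 to 180 bp (24.6% to 26.6%). Position still mattered, since beside another Kupffer peak the shares were 33.4% (32.6% to 34.1%) and 31.9% (30.8% to 33.0%), with overlapping intervals. The difference lay in pairs of narrow peaks: of all Kupffer peaks up to 151 bp wide, 21.4% had an endothelial partner of the smallest width (21.0% to 21.8%) and 14.4% a wider one (14.1% to 14.8%), against 6.45% (6.06% to 6.86%) and 22.3% (21.6% to 22.9%) of those of 152 to 180 bp. Sites at the calling limit in both lists stay open. Their test was the share of 151 bp endothelial partners, 59.8% (58.9% to 60.6%) against 22.5% (21.2% to 23.8%). It was written beforehand, with a bound close to the observed share of 151 bp peaks among all shared endothelial peaks, 27.3%. The test sees only peaks that are already shared and so decides nothing, and the lists hold no peak height. Sharply positioned sites called at the same place in every library stay open too: the centres of pairs of 151 bp peaks lay 28 bp apart (27 to 28) against 24.5 bp (24 to 24.5) in other shared pairs, no closer, but by less than the 10 bp set beforehand as the bound against it. The way libraries were merged, which also sets widths, is not given and was not tested.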
